A study of Homo sapiens with 3 samples.

How the data were processed

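The samples were 3 human cell lines, HT-29 with IFN-γ, MCF10A and MDA-MB-436, grouped by the submitters' labels into 3 groups of 1 array each. Biotin-labelled material from total RNA was hybridised to exon arrays, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 for each of 18708 transcript clusters and array. The method of summary, the background correction and the normalization between arrays were not given in the sources used here; the submitters' processing notes list the genome build hg19. The columns did not share a distribution, with 95th percentiles of 1214 in HT-29, 1197 in MCF10A and 966 in MDA-MB-436, so the values were not quantile normalized in the form analysed here. Whether they were normalized at an earlier step, such as before summary to clusters, or scaled in another way is unknown, and a share of small differences can come from that.

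Clusters were named from the platform annotation, with symbols updated through gene identifiers against the RefSeq annotation of GRCh38.p14, which served only for names and for the order of genes. Of the clusters, 17608 were listed with a symbol, 14733 with a single one, of which 14705 were matched by identifier, 2875 had several symbols and were not named, and 1100 were unnamed here. For the 323 clusters beyond the first of a gene, the cluster with the highest mean over the 3 arrays was used, which left 14410 genes. TP63, KRT5 and MTAP, chosen in advance, had no cluster with a single symbol and were not analysed here. Some other genes chosen in advance are not reported here. Values were given per transcript cluster and not per exon, so splice forms were not analysed here, and related genes can share probe signal.

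Intensities were log2 transformed as deposited and differences taken between arrays. Background was the 95th percentile of the intensities of 228 olfactory receptor genes, 29.9; their median was 5.92 and their highest value 101. A gene was counted when its log2 difference was at least 2, a fold of 4, and its higher intensity was above background. A fold against an array under background was computed against the background and is a lower bound, and no fold is given where both were under it. No test was made, because each group had 1 array, and the number of arrays limits the precision.

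Before the data were examined, 27 gene lists were fixed: IFN-γ response, type I interferon stimulated, class I and class II presentation, intestinal, goblet and mucin, basal and luminal mammary, mesenchymal, epithelial adhesion, desmosome and cornified envelope, p53 targets, mitosis, S phase, glucocorticoid, EGFR and MAPK feedback, cAMP, cholesterol, hypoxia, WNT, splicing regulators, cancer-testis, leukocyte, fibroblast, endothelial, neural and ribosomal genes. For each list and comparison the median log2 difference was set against 10000 random lists of the same size, matched on mean expression in 20 bins; the percentile describes these arrays and is not a p-value. Intervals are 95% ranges over 2000 resamplings of a list's genes. Lists can share members, such as ENO2 on the hypoxia and neural lists. Shared members were not removed, so lists are not all separate findings. Comparisons share arrays, so no overlap or correlation between them is given. Named genes followed a rule fixed at the same time: per comparison the 8 largest differences in each direction past 4-fold, per list up to 4 members with the largest differences and up to 2 against the list's direction, 22 single genes, and per line the 6 genes furthest above both other arrays. Largest and furthest refer to measured log2 differences, which can rest on values under background.

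The alternatives were quantile normalization, median centring, no filter and a filter at the 99th percentile of olfactory receptor genes, folds of 2 and 8, the median over a gene's clusters, lists restricted to members above background and 10 bins. Setting values under background to the background was added after the data were seen. The counting and list steps were run on data simulated for MDA-MB-436 minus MCF10A over 14410 genes. Of the genes changed 8-fold, 100% were recovered, 0 unchanged genes passed 4-fold, and 3 of 100 unchanged lists lay outside the central 95% of random lists. The changed genes all lay well above background, and the simulated noise was smaller than the spread of olfactory receptor genes between these arrays. Recovery was therefore fixed in advance, and the run checks the code, not the error rate. In that comparison the olfactory receptor genes had an SD of 0.777. Of these 228 genes, 4 passed 4-fold without the background filter, against 7 for HT-29 minus MCF10A and 8 for HT-29 minus MDA-MB-436. With the filter 0 passed in any comparison. The background was set from these same genes, so that 0 was largely fixed in advance and gives no error rate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.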

Results

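Total RNA from 3 human cell lines was measured on exon arrays, with 1 array per line. HT-29, a colon adenocarcinoma line, had been exposed to interferon gamma (IFN-γ), a cytokine that activates antiviral and antigen presentation genes, at 200 U/ml for 24 h. MCF10A, a non-tumorigenic mammary epithelial line, was grown in a medium that contained epidermal growth factor, hydrocortisone, cholera toxin and insulin, and MDA-MB-436, a breast adenocarcinoma line, in L-15 medium with serum. An HT-29 culture without IFN-γ was not analysed here, so each difference between HT-29 and a mammary line joins the effects of line, medium and cytokine. With 1 array per line there was no replicate spread, and no test, p-value or standard error could be given; the differences describe these 3 arrays.

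Each array gave an intensity for 18708 transcript clusters, of which 14410 genes with a symbol of their own were compared. The median intensity was 75.9 in HT-29, 75.1 in MCF10A and 81 in MDA-MB-436, and the highest was 6611, 6059.7 and 6505. Olfactory receptor genes, which are expressed mainly in olfactory tissue, set the background: the 95th percentile of their intensities was 29.9. Above it lay 9596 genes in HT-29, 9362 in MCF10A and 9907 in MDA-MB-436. Across genes, which are not independent replicates, log2 intensities correlated at a Pearson r of 0.908 between the mammary lines, 0.880 between HT-29 and MCF10A and 0.864 between HT-29 and MDA-MB-436. GAPDH and ACTB, a glycolytic enzyme and a cytoskeletal actin used as reference genes, differed by at most 1.08-fold and 1.07-fold between arrays, and the sign of their differences from MDA-MB-436 turned under quantile normalization. Counts of genes past 4-fold use the measured intensities. Where the dimmer array was under background, the fold of a named gene is a lower bound computed against the background intensity and is written as "at least". A fold against a value just above background, such as that of CAV1 in HT-29 at 33.7, is close to such a bound. Intervals beside list medians come from resampling the genes of a list and describe how its members vary, not experimental error.

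**Figure D1:**
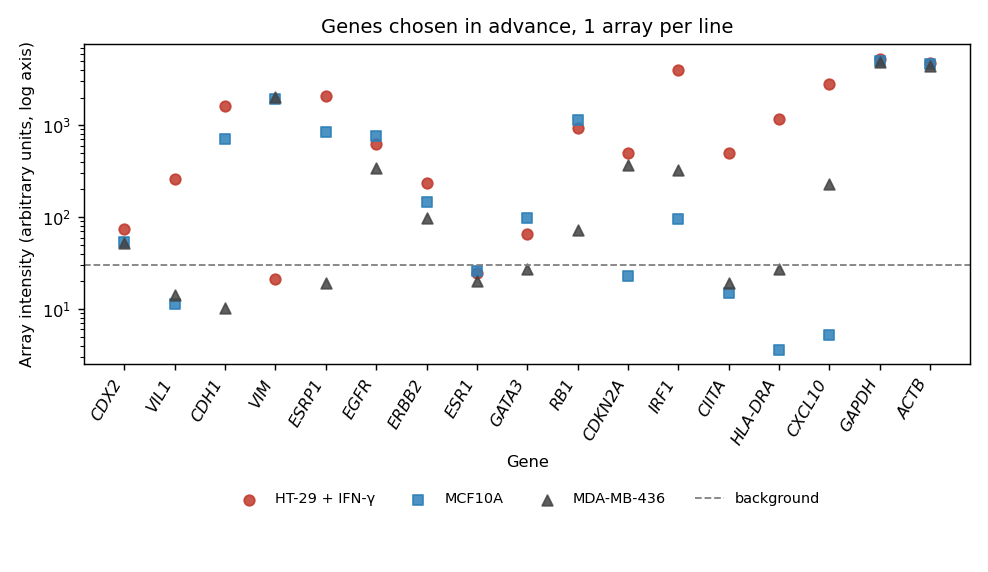
Array intensity (arbitrary units, log axis) of 17 genes chosen in advance, 1 point per array, with the background of 29.9 as a dashed line. CDH1 and ESRP1 lie under background in MDA-MB-436 alone, VIM in HT-29 alone and CDKN2A in MCF10A alone, whereas GAPDH and ACTB overlap in all 3 arrays.

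MDA-MB-436 and MCF10A set a breast cancer line beside a non-tumorigenic mammary line. Genes of basal epithelium and of cell adhesion were lower in MDA-MB-436, and interferon-stimulated genes and part of the mesenchymal genes were higher. In all, 525 genes were at least 4-fold higher and 290 at least 4-fold lower. Setting values under background to the background, a choice made after the data were seen, left 307 genes higher.

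Of 21 measured genes of basal mammary epithelium, 11 were at least 4-fold lower in MDA-MB-436 and 0 higher, with a median log2 difference of -2.22 (interval -4.03 to -1.16). KRT14, a keratin of basal cells, had an intensity of 3732 in MCF10A and 17.6 in MDA-MB-436, at least 125-fold lower. SERPINB5, which encodes the serpin maspin, was at least 63.3-fold lower and the P-cadherin gene CDH3 at least 41.4-fold lower. The epithelial adhesion and polarity list had 15 of 35 genes at least 4-fold lower and 0 higher (median -1.58, interval -2.46 to -0.92). CDH1, which encodes E-cadherin, was at least 23.9-fold lower, at 10.3 against 716. The tight junction gene CLDN7 and the epithelial splicing regulator ESRP1 were at least 39-fold and at least 27.9-fold lower. Among 27 genes of desmosomes and the cornified envelope, 12 were at least 4-fold lower (median -1.69, interval -3.55 to -0.80), among them the desmosomal cadherin DSG3 at least 34.6-fold and cystatin A, CSTA, at least 32.1-fold. For these 3 lists, 0 of 10000 random lists matched on expression lay as low. The luminal list was also low (median -0.39, interval -0.59 to -0.18, or -0.18 with the background floor; 11 of 10000 random lists as low), but only 1 of its 27 genes, the mucin gene MUC1, was at least 4-fold lower, and PRLR, the prolactin receptor gene, was at least 5.68-fold higher.

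Of 41 mesenchymal genes, 12 were at least 4-fold higher in MDA-MB-436 and 2 lower (median 0.45, interval 0.076 to 1.32, or 0.29 with the floor; 6 of 10000 random lists as high). The N-cadherin gene CDH2 had an intensity of 708 against 33.9, 20.9-fold higher. The matrix proteoglycan gene BGN was 26.7-fold higher, the matrix protease gene MMP2 at least 22.5-fold higher and the bone morphogenetic protein antagonist GREM1 at least 12.4-fold higher. Another matrix protease gene, MMP14, was at least 5.26-fold lower. VIM, which encodes the intermediate filament vimentin, was at 2038 and 1933, a difference whose sign turned with median centring.

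The labels name no IFN-γ for either mammary culture. Of the type I interferon stimulated genes, 17 of 31 were at least 4-fold higher in MDA-MB-436 than in MCF10A and 0 lower, with a median log2 difference of 2.63 (interval 0.999 to 3.89). IFI6 was at 3409.8 against 56.8, 60.1-fold higher. IFI44L was at least 37.8-fold higher and BST2, which encodes the antiviral membrane protein tetherin, at least 29.4-fold higher, whereas IFIT5 was 2.13-fold lower. The list of IFN-γ response genes, which shares no member with it, had 13 of 50 genes at least 4-fold higher and 1 lower (median 1.11, interval 0.63 to 1.68, or 0.71 with the floor). The adhesion molecule gene ICAM1 was 14-fold higher and the chemokine gene CXCL10 at least 7.64-fold higher, while TRIM22 was at least 7.04-fold lower. The class I presentation genes were higher by less (median 0.62, interval 0.29 to 1.09), with none of the 15 past 4-fold. In all 3 lists 0 of 10000 random lists lay as high, but genes that the class I list may share with the others were not removed. For the 9 class II presentation genes the median was 0.67 and 180 random lists lay as high. That list left the upper tail after quantile normalization (percentile 91.9) and with the background floor (percentile 66.8), and the class II gene HLA-DRA was under background in both lines.

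The tumor suppressor gene RB1 was at 72.4 in MDA-MB-436 against 1155 in MCF10A, 16-fold lower by measured intensity and under the highest olfactory receptor value of 101. CDKN2A, which encodes a cyclin-dependent kinase inhibitor, was at 371 against 23, at least 12.4-fold higher. Of 28 p53 target genes, 5 were at least 4-fold lower and 0 higher (median -0.88, interval -1.72 to -0.30; 0 of 10000 random lists as low). SFN, which encodes 14-3-3 sigma, was 15.6-fold lower, whereas GADD45A was 3.56-fold higher. Mitotic genes had a median of -0.58, S phase genes of -0.45, cholesterol synthesis genes of -0.85 and ribosomal protein genes of -0.57, and no member of these 4 lists was past 4-fold. As low as these lay 82, 646, 8 and 50 of 10000 random lists, whose own medians were -0.24, -0.21, -0.19 and -0.26, so part of each size is shared by genes of the same level. After quantile normalization the mitotic, S phase and ribosomal medians were -0.31, -0.24 and -0.32.

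The glucocorticoid response list, of interest because hydrocortisone was in the MCF10A medium, had 5 of 19 genes at least 4-fold lower in MDA-MB-436 and 2 higher (median -0.57, interval -1.45 to -0.076, percentile 1.6, or a median of -0.33 at percentile 4.2 after quantile normalization). The sodium channel subunit gene SCNN1A was at least 31.3-fold lower, the transcription factor gene TFCP2L1 20.6-fold lower and ZBTB16 at least 8.46-fold lower. LCN2 was 8.34-fold higher and TNFAIP3 7.54-fold higher. In HT-29, SCNN1A was at 723, near the 935 of MCF10A, whereas TFCP2L1 and ZBTB16 were at 36.9 and 30.6. An effect of hydrocortisone was not tested. Genes of EGFR and MAPK feedback had no common direction, with 2 higher and 2 lower past 4-fold (median -0.28, percentile 29.8). The phosphatase gene DUSP6 was 9.76-fold lower and the cytokine gene LIF at least 11.3-fold higher. The cAMP and CREB list had a median of -0.50 (percentile 0.25), which was 0 at percentile 46.6 with the background floor, and 1 higher and 1 lower past 4-fold. Hypoxia and glycolysis genes had a median of 0.18 at percentile 99.7, or 0.39 after quantile normalization and 0.071 after centring, with the enolase gene ENO2 at least 18.7-fold higher and DDIT4 6.55-fold lower. WNT targets had a median of 0.40 at percentile 98.5, with none of 21 past 4-fold, and moved inside the central 95% of random lists after quantile normalization (94.0), over members above background (74.8) and with the floor (50.8). Goblet and mucin genes had a median of -0.18 at percentile 1.2, which was 18.7 over members above background and 43.6 with the floor. Intestinal genes had a median of -0.032 at percentile 9.5, with 1 of 30 at least 4-fold higher and 2 lower.

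Median centring moved the median of MDA-MB-436 minus MCF10A by 0.11 on the log2 scale. Markers of other cell types were mostly dim: the medians of the leukocyte, fibroblast and endothelial lists were 0.36, 0.15 and 0.22, inside the central 95% of random lists, and quantile normalization turned the sign of the fibroblast and endothelial medians.

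**Figure D2:**
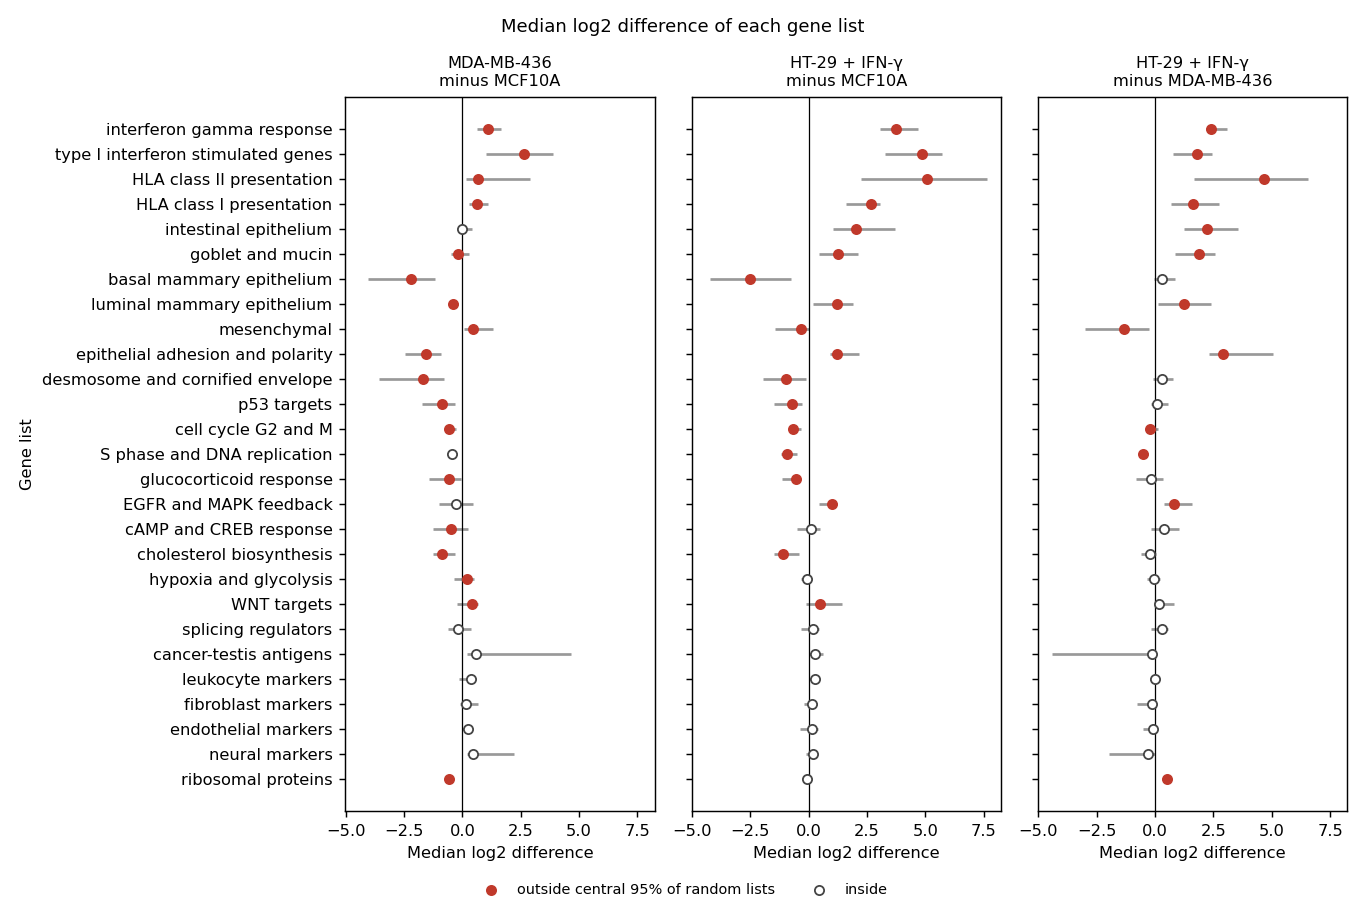
Median log2 difference of 27 gene lists fixed in advance, in the 3 comparisons of arrays, with intervals from resampling each list's genes as grey lines. Filled points lie outside the central 95% of 10000 random lists matched on expression, which held for 49 of 81 medians; the highest point is class II presentation in HT-29 with IFN-γ minus MCF10A, at 5.06.

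HT-29 with IFN-γ was compared with MCF10A, and by list median the largest differences were those of interferon response, antigen presentation and intestinal genes on the higher side and basal, cholesterol synthesis and desmosome genes on the lower side. There were 624 genes at least 4-fold higher and 504 at least 4-fold lower. The largest difference was that of LYZ, which encodes lysozyme, at 4319.6 against 4.82, at least 144-fold higher. The chemokine genes CXCL10 and CXCL11 were at least 93.3-fold and at least 76-fold higher.

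Of 50 measured IFN-γ response genes, 42 were at least 4-fold higher in HT-29 with IFN-γ than in MCF10A and 0 lower, with a median log2 difference of 3.76 (interval 3.06 to 4.67). The transcription factor gene IRF1 was at 3961 against 94.9, 41.7-fold higher. The guanylate binding protein genes GBP4 and GBP5 were at least 65.8-fold and at least 30.9-fold higher, although probes for such related genes can share signal. Of 31 type I interferon stimulated genes, 29 were at least 4-fold higher (median 4.84, interval 3.26 to 5.72), including OAS2 at least 54.1-fold and BST2 at least 40.6-fold. Class II presentation genes were higher in 8 of 9 cases past 4-fold (median 5.06, interval 2.23 to 7.64). HLA-DRA was at 1169 against 3.63, at least 39.1-fold higher, and CD74, the invariant chain gene, was at least 112-fold higher. CIITA, the coactivator of class II genes, was at 496 against 14.9, at least 16.6-fold higher. Of 15 class I presentation genes, 10 were at least 4-fold higher (median 2.68, interval 1.62 to 3.06), among them the peptide transporter gene TAP1 at 9.49-fold and NLRC5, the class I coactivator, at 11.4-fold, while the chaperone gene CALR was 1.33-fold lower. For all 4 lists, 0 of 10000 random lists lay as high.

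**Figure D3:**
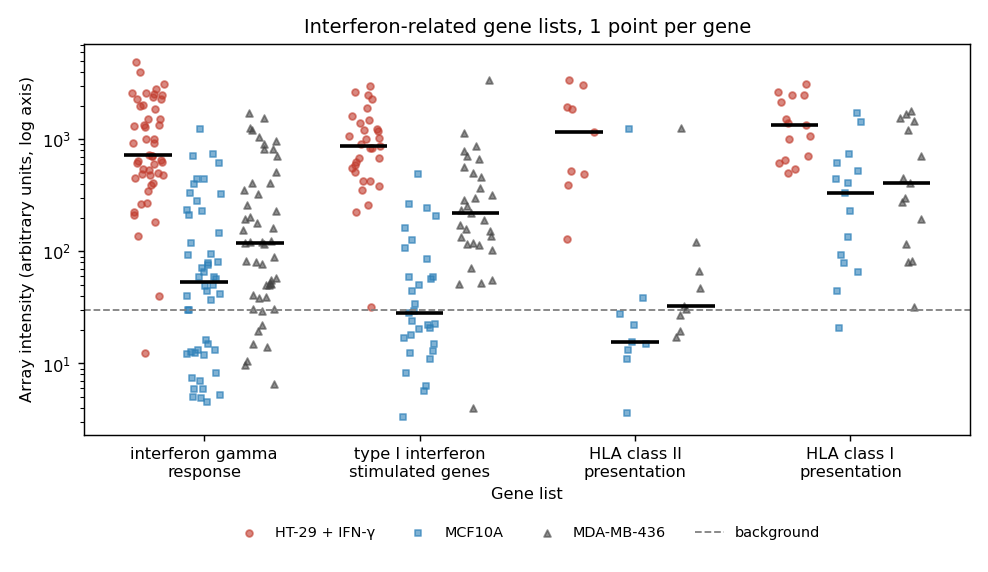
Array intensity (arbitrary units, log axis) of the members of 4 interferon-related gene lists, 1 point per gene and array, with the list median as a black bar and the background of 29.9 as a dashed line. The median of the type I list was 879 in HT-29 with IFN-γ, 218 in MDA-MB-436 and 28 in MCF10A, and that of the class II list 1169, 32.3 and 15.4.

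Of 30 intestinal epithelium genes, 15 were at least 4-fold higher in HT-29 and 2 lower (median 2.04, interval 1.03 to 3.68, 1.05 with the floor and 3.34 over members above background; 0 of 10000 random lists as high). The galectin gene LGALS4 was at 2372 against 14, at least 79.3-fold higher, and VIL1, which encodes the brush border protein villin, at least 8.81-fold higher. ANPEP, the aminopeptidase N gene, and CA2, a carbonic anhydrase gene, went the other way, at least 81.2-fold and 4.75-fold lower. CDX2, an intestinal transcription factor gene, was at 74.8 in HT-29 and 53.2 in MCF10A, a 1.41-fold difference, and at 51.9 in MDA-MB-436. These values lie under the highest olfactory receptor value of 101, so whether CDX2 transcript was present in any of the lines stays open. Goblet and mucin genes had 6 of 16 members at least 4-fold higher (median 1.26, 0.34 with the floor and 2.06 over members above background), among them the mucin gene MUC13 at least 30.01-fold. GPX2, a glutathione peroxidase gene, was at least 105-fold higher.

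Of 21 basal genes, 12 were at least 4-fold lower in HT-29 and 0 higher (median -2.51, interval -4.23 to -0.77; 0 of 10000 random lists as low). KRT14 was at least 125-fold lower and CAV1, which encodes caveolin 1, 111-fold lower. Of 41 mesenchymal genes, 9 were at least 4-fold lower and 1 higher (median -0.32, percentile 0.08, but -0.56 after quantile normalization, -1.24 over members above background and 0 at percentile 46.6 with the floor). The transcription factor gene SNAI2 was at 12.4 against 4078, at least 136-fold lower, and VIM was at least 64.6-fold lower, while BGN was 6.92-fold higher. The epithelial adhesion list was higher, with 13 of 35 genes past 4-fold and 0 lower (median 1.21, interval 0.92 to 2.15; 0 of 10000 random lists as high). GRHL2, an epithelial transcription factor gene, was at least 16.4-fold higher and RAB25 at least 16.5-fold higher. CDH1 and ESRP1 were expressed in both lines and were 2.24-fold and 2.49-fold higher. The luminal list had 8 of 27 genes at least 4-fold higher (median 1.20 at percentile 100, or 0 at percentile 47.8 with the floor), with KRT19 at 41-fold and the receptor gene ERBB3 at 18.9-fold. Its largest difference was that of AGR2, at least 23.4-fold, which is also on the intestinal list. ERBB3 is also on the epithelial adhesion list, so these lists are not separate findings. The desmosome and cornified envelope list had 8 of 27 genes lower and 1 higher past 4-fold (median -0.98, 0 of 10000 random lists as low), the higher gene being the kallikrein KLK6 at 105-fold.

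S phase genes were lower in HT-29 with IFN-γ (median -0.93, interval -1.18 to -0.50), as were mitotic genes (median -0.68, interval -0.86 to -0.33), with 0 of 10000 random lists as low for either and 1 gene past 4-fold, CCNE2, a cyclin gene, at 4.44-fold lower. MKI67 was at 969 against 858. The p53 targets had 4 of 28 genes lower and 1 higher past 4-fold (median -0.73, 0 of 10000 random lists as low), with ZMAT3 8.69-fold lower and SESN2 11.9-fold higher. Cholesterol synthesis genes had a median of -1.10 (interval -1.47 to -0.41; 1 of 10000 random lists as low), with the sterol oxidase gene MSMO1 6.58-fold lower. The glucocorticoid list had a median of -0.53 (61 of 10000 random lists as low), with TFCP2L1 41-fold lower and LCN2 41.8-fold higher. EGFR and MAPK feedback genes were higher (median 0.99, interval 0.43 to 1.21; 0 of 10000 random lists as high), with the ligand gene EREG 12.3-fold higher and the cytokine gene IL1A at least 47.3-fold lower. WNT targets had a median of 0.48 at percentile 99.4, which was 97.3 over members above background and 48.6 with the floor. Among them RNF43, a ubiquitin ligase of WNT receptors, was 14.3-fold higher, AXIN2 at least 6.72-fold higher and LEF1 at least 7.43-fold lower. The cAMP, hypoxia and ribosomal lists had medians of 0.078, -0.073 and -0.064 and lay inside the central 95% of random lists, as did the leukocyte, fibroblast and endothelial lists at 0.28, 0.14 and 0.14, of which quantile normalization turned the fibroblast and endothelial signs. LYZ, counted among the leukocyte markers, is also made by epithelia.

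HT-29 with IFN-γ was also compared with MDA-MB-436. Epithelial adhesion, intestinal, class II and IFN-γ response genes were higher in HT-29, and mesenchymal genes were higher in MDA-MB-436. There were 606 genes at least 4-fold higher in HT-29 and 674 at least 4-fold lower. LYZ was at least 144-fold higher. Lower in HT-29 were the cancer-testis gene MAGEA4, at least 67.2-fold, and BNIP3, a mitophagy receptor gene, at 6.31 against 1439, at least 48.1-fold.

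All 35 measured epithelial adhesion genes were higher in HT-29, 25 of them past 4-fold (median 2.89, interval 2.33 to 5.05; 0 of 10000 random lists as high). CDH1 was at 1607 against 10.3, at least 53.7-fold higher, ESRP1 was at least 69.4-fold higher and CLDN4 at least 69.5-fold higher. Of 41 mesenchymal genes, 18 were at least 4-fold lower in HT-29 and 0 higher (median -1.35, interval -3.00 to -0.25, or -2.23 over members above background; 0 of 10000 random lists as low), with VIM at least 68.1-fold, CDH2 at least 23.7-fold and MMP2 at least 22.5-fold lower. Intestinal genes had 16 of 30 members higher and 1 lower past 4-fold (median 2.21, interval 1.25 to 3.56, 1.30 with the floor and 3.48 over members above background), and goblet and mucin genes 8 of 16 higher (median 1.90, or 0.96 with the floor), with 0 of 10000 random lists as high for either. TSPAN8, a tetraspanin gene, was at least 24.7-fold higher and ANPEP at least 34.7-fold lower. The luminal list had 12 of 27 genes higher and 1 lower past 4-fold (median 1.26, or 2.06 over members above background, 0 of 10000 random lists as high), with KRT19 63.9-fold higher. Its largest difference was again that of AGR2, shared with the intestinal list, at least 23.4-fold. Basal genes had a median of 0.29 and desmosome genes of 0.29, at percentiles 84.8 and 93.8. After quantile normalization these percentiles were 98.0 and 98.6, and the desmosome percentile over members above background was 99.4. CAV1 was 72.5-fold lower in HT-29 and KLK6 at least 106-fold higher.

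Of 50 IFN-γ response genes, 34 were at least 4-fold higher in HT-29 with IFN-γ than in MDA-MB-436 and 1 lower (median 2.39, interval 2.18 to 3.07). IRF1 was 12.1-fold higher, CXCL9 at least 23.9-fold higher and IDO1, which encodes a tryptophan-degrading enzyme, at least 16.1-fold higher, whereas PDCD1LG2, which encodes an immune checkpoint ligand, was at least 2.96-fold lower. Type I interferon stimulated genes had 13 of 31 members higher and 1 lower past 4-fold (median 1.81, interval 0.75 to 2.45). IFITM1 was 32.1-fold higher, whereas HERC5 was at 31.7 against 157, 4.95-fold lower, and RSAD2 was at 386 and 497. Class II genes had 7 of 9 members past 4-fold higher (median 4.68, interval 1.68 to 6.57), with CD74 49.8-fold higher and CIITA at least 16.6-fold higher, and class I genes 7 of 15 (median 1.63, interval 0.66 to 2.74), with TAP1 7.75-fold higher. For these 4 lists 0 of 10000 random lists lay as high.

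RB1 was at 930.1 in HT-29, 12.9-fold above MDA-MB-436. The p53 targets had a median of 0.088 (percentile 44.7), with SFN 5.60-fold higher in HT-29. S phase genes had a median of -0.53 and mitotic genes of -0.23 (-0.36 after quantile normalization, -0.14 after centring), with 1 and 23 of 10000 random lists as low and no member past 4-fold; MKI67 was nonetheless 2.21-fold higher in HT-29. Feedback genes of EGFR and MAPK were higher (median 0.82, 3 of 10000 random lists as high), with DUSP6 16.9-fold and EGR1 10.7-fold higher, and IL1A was at least 64.6-fold lower. Ribosomal protein genes had a median of 0.50 (141 of 10000 random lists as high), which was 0.19 after quantile normalization, and none was past 4-fold. The glucocorticoid, cAMP, cholesterol, hypoxia and WNT lists, at medians of -0.19, 0.36, -0.22, -0.041 and 0.17, lay inside the central 95% of random lists, except that the cAMP list was at percentile 98.8 after quantile normalization, and centring turned the sign of the hypoxia median. The leukocyte, fibroblast and endothelial lists were at 0.0022, -0.13 and -0.10. The fibroblast list passed to percentile 2.0 when only members above background were taken, and quantile normalization turned the signs of the leukocyte and endothelial medians.

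Some genes stood at least 4-fold apart from both other arrays by their measured intensities. HT-29 with IFN-γ had 353 genes above and 256 below both mammary lines, MCF10A 127 above and 157 below, and MDA-MB-436 310 above and 121 below. With values under background set to the background, MCF10A had 89 genes below and MDA-MB-436 had 187 above. The rule fixed in advance named the 6 genes per line with the largest measured difference, dim values included. In HT-29 these were LYZ, GPX2, TSPAN8, MUC13, NMUR2, a neuropeptide receptor gene, and AGR2, with NMUR2 at 1992 and at least 66.6-fold above the higher of the other lines. In MCF10A they were KRT14, EPGN, an epidermal growth factor family ligand gene, MFAP5, SLC43A3, CLCA2 and DSG3, with EPGN at 773 and at least 25.8-fold above. In MDA-MB-436 they were MAGEA4, LRRN1, OLR1, DPYSL3, CCL2 and TSHZ3, with the chemokine gene CCL2 at 1172 and at least 39.2-fold above. All 18 were compared with values under background, so their order is not a ranking by fold: TSHZ3 was at least 2.91-fold above the other lines, whereas KLK6, not among the 6 of HT-29, was 105-fold above MCF10A and at least 106-fold above MDA-MB-436.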

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

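The background floor was chosen after the data were seen; the other settings were fixed before. The 12 counts stayed within 1.5 times their main value under quantile normalization, median centring, both filters and the median over clusters. The fold threshold moved all 12 by construction. At 2-fold there were 1261 higher and 1258 lower genes for MDA-MB-436 minus MCF10A, 1465 and 1454 for HT-29 minus MCF10A, 1657 and 1580 for HT-29 minus MDA-MB-436, and, set apart above and below, 939 and 768 in HT-29, 538 and 457 in MCF10A and 710 and 477 in MDA-MB-436. At 8-fold the numbers, in that order, were 239 and 132, 332 and 237, 292 and 329, then 175 and 105, 58 and 54, and 137 and 52. With the floor, MDA-MB-436 minus MCF10A had 307 higher genes, MCF10A 89 set apart below and MDA-MB-436 187 above, because folds against dim values shrink to bounds.

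Calls of the 81 list medians against random lists all stayed on their side with centring, the median over clusters and 10 bins. Quantile normalization ended 3 calls and added 3, the restriction to members above background ended 3 and added 6, and the floor ended 7. That restriction gave 80 medians, since no cancer-testis gene was above background in HT-29 or MCF10A. A member passed it through the brighter of the arrays compared, so it favours members that differ. Under quantile normalization the median moved to -0.29 for intestinal, -0.0067 for endothelial and -0.32 for ribosomal genes in MDA-MB-436 minus MCF10A, to -0.017 for cancer-testis and 0.047 for leukocyte genes in HT-29 minus MCF10A, and to -0.36 for mitotic and 0.19 for ribosomal genes in HT-29 minus MDA-MB-436. Centring moved the ribosomal median of MDA-MB-436 minus MCF10A to -0.67. Over members above background the medians were 0.63 for leukocyte, -0.029 for endothelial and 3.29 for neural genes in MDA-MB-436 minus MCF10A, -0.63 for endothelial genes in HT-29 minus MCF10A, and -0.21 for leukocyte, -0.77 for fibroblast and -3.07 for neural genes in HT-29 minus MDA-MB-436. With the floor they were 0.048 for class II and 0 for cancer-testis, endothelial and neural genes in MDA-MB-436 minus MCF10A, 0.34 for goblet and 0 for luminal, cancer-testis and leukocyte genes in HT-29 minus MCF10A, and 0 for cancer-testis genes in HT-29 minus MDA-MB-436. The floored zeros arise because the middle members lie under background on both arrays; the cause of the other moves was not tested. No named gene past 4-fold changed sign. Signal over background limits lists of dim genes most, such as the cancer-testis list, of which 3 of 9 members were above background in MDA-MB-436 or MCF10A.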

Other observations

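Several further groups of genes held members that were higher in MDA-MB-436 than in either other line. Of 9 measured cancer-testis genes, which are normally active in germ cells, 3 were at least 4-fold above MCF10A by measured intensity (median 0.59, percentile 93.4): MAGEA4 at 2009 against 5.61, MAGEA10 at 181 against 7.12, and MAGEC1 at 40.1 against 8.84, only at least 1.34-fold against background, although probes of the MAGE family can share signal. In HT-29, none of the 9 was above background (median against MCF10A 0.25, against MDA-MB-436 -0.14). Of 22 neural genes, 7 were at least 4-fold higher in MDA-MB-436 than in MCF10A and 7 were at least 4-fold lower in HT-29 than in MDA-MB-436 (medians 0.44 and -0.32, percentiles 95.5 and 2.7; HT-29 minus MCF10A 0.18). Over the 11 and 10 neural genes above background on the brighter array these medians were 3.29 and -3.07. Over the 3 such cancer-testis genes they were 4.67 and -4.42. Those 3 genes passed only through MDA-MB-436, so the filter fixed the sign of their medians in advance. Only 6 of 22 neural genes were above background in HT-29 or MCF10A, so the filter also favours neural genes that are high in MDA-MB-436. With the background floor all 4 medians were 0. The ubiquitin hydrolase gene UCHL1 was at 1376, against 25.4 in MCF10A and 22.6 in HT-29, and NCAM1, a neural adhesion molecule gene, at 229, 18 and 15.9. The complement genes C1S and C1R, listed with the fibroblast markers, were at 1723 and 1909.8 in MDA-MB-436, 150.3 and 111 in HT-29 and 16.3 and 26.3 in MCF10A.

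The splicing regulator list had no common direction, with medians of -0.17 for MDA-MB-436 minus MCF10A, 0.17 for HT-29 minus MCF10A and 0.29 for HT-29 minus MDA-MB-436, all inside the central 95% of random lists; quantile normalization turned the sign of the value for MDA-MB-436 minus MCF10A to 0.034. Single members differed widely. ESRP1 was at 2075 in HT-29, 834 in MCF10A and 19.3 in MDA-MB-436, and RBM47 at 2591, 216 and 610.4. QKI, a splicing regulator linked to mesenchymal cells, was at 7.03, 152 and 166, so that MCF10A had both ESRP1 and QKI above background. MCF10A also had CDH1 at 716 together with VIM at 1933 and SNAI2 at 4078.

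The tests that follow were chosen after the patterns were seen, except those without neighbours that share a name stem, which were fixed before their result. Interferon-stimulated genes were higher in MDA-MB-436 than in MCF10A although the labels give neither line IFN-γ. Mixing of HT-29 RNA into the MDA-MB-436 sample would bring intestinal transcripts in the same share, but of the HT-29 excess over MCF10A a median of 0.145% was present for 13 intestinal genes (interval -0.25 to 1.18) and 27.4% for 23 interferon-stimulated genes (interval 7.57 to 61.9); the abundant LGALS4 was at 2372 in HT-29 and 19.9 in MDA-MB-436, DPP4 alone was past 4-fold, and 2 of the 13 genes are also on another list. Between-array scaling would act alike on genes of one level. After quantile normalization the list median was 2.52 with an interval of 0.96 to 3.86, above the highest of 10000 random lists matched on level, 0.62. A first criterion, an interval above a log2 difference of 1, was not met, and it was replaced by this one after that result was seen. The main values had already put 0 of 10000 random lists as high, so the outcome of the second criterion was largely known beforehand. An interferon gene expressed by the cells was sought, and 0 of 9 measured interferon genes were above background and 2-fold above MCF10A, with a highest intensity of 14.4 in MDA-MB-436; since an interferon may act at levels below background or come from a gene not analysed here, this does not decide. Mixing is argued against, and scaling only by a criterion set after the result. A biological difference between the lines is a hypothesis, not separated here from culture conditions, which were not tested.

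Neighbouring genes differed together. In medians over 25 neighbouring genes of the log2 difference from the mean of the other 2 arrays, the SD was 0.327 in HT-29, 0.306 in MCF10A and 0.361 in MDA-MB-436 over 10690 genes, against a highest value of 0.194, 0.178 and 0.181 in 1000 shuffles, so a random order of genes is argued against. Without genes that share a name stem with a near neighbour the SDs were 0.319, 0.299 and 0.352 over 9595 genes, against 0.194, 0.180 and 0.182. Neighbours with a shared name stem therefore do not account for the pattern. Paralogs with unlike names stayed in and were not tested. In windows named after their values were seen, the lowest in HT-29, from LOXL2 to INTS9 (median -1.48), and the highest in MCF10A, from STC1 to DUSP4 (1.36), shared 22 of 25 genes and are not separate findings, with a median HT-29 minus MCF10A of -1.56 and MDA-MB-436 minus MCF10A of -1.04 over the shared genes; the highest in HT-29, at 1.22, held HOXB genes, the highest in MDA-MB-436, at 1.35, IFI44L and IFI44, and the lowest in MCF10A and MDA-MB-436 were at -0.95 and -1.04. Copy number differences between the lines may underlie part of this, as may domains of genes that are regulated together. Neither was tested, and the build of the gene order differs from that of the arrays. The shuffles used the values as deposited and did not match genes on level, so a difference between arrays tied to level was not separated either.

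RB1 in MDA-MB-436 was 12.9-fold below the lower of the other lines by measured intensity. Loss of a wider region to the same extent as at RB1 would lower its neighbours as far. By measured intensity 1 of the 6 nearest genes above background, LPAR6, was 4-fold lower or more. It was at 4.82 against 33 in HT-29 and 108 in MCF10A, a bound of only 1.10-fold against background. RCBTB2, at 33.9 in HT-29, was likewise too near background to show such a fall. The brighter neighbours did not fall as far as RB1. A wider loss of smaller extent, such as of 1 copy, cannot be excluded by a 4-fold rule. LPAR6 lies within RB1 in the RefSeq annotation, and ITM2B, the next lowest, was 1.77-fold below the lower of the other lines. Against MCF10A alone all 6 neighbours were lower, among them SUCLA2 at 310 against 1105 and MED4 at 119 against 312. Against HT-29, SUCLA2 and RCBTB2 were higher. A change confined to RB1, or lower transcription of it, is a candidate explanation that was not tested. The RB1 intensity of 72.4 was above the background of 29.9 but under the highest olfactory receptor value of 101, so whether RB1 transcript was present at all stays open.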
